A study of Mus musculus with 33 samples.

How the data were processed

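Total RNA of the right hippocampus of 33 male mice on a mixed SJL × C57BL/6J background was labelled with biotin and hybridised to Affymetrix MOE430 2.0 arrays, 1 array per animal, per the labels' protocols. Groups were taken from the labels: 11 wild-type animals with vehicle, 11 Tg2576 animals with vehicle and 11 Tg2576 animals with TO901317. The animals were perfused 1 hour after the last dose, per the labels. The deposited values are array intensity on a linear scale, made by the authors with MAS5, the tool the submitters name. The version of MAS5 and its settings are not given in the sources used here. From the values themselves, the mean signal after trimming 2 percent at each end was 99.97 on every array, so the arrays had been scaled to a common mean but not made equal in distribution. No scan dates or detection calls were used here.

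The table holds 45101 probe sets, of which 64 are Affymetrix controls and were left out of the tests. Probe sets were named from the platform annotation, which can be old: 34945 name 1 gene, 932 name several and 9160 carry no name here. Only probe sets with 1 gene were used at the gene level. Gene neighbours and synonyms came from the RefSeq table of assembly GRCm38.p6, whose coordinates are not used here since no build is named by the authors.

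The test used log2(signal + 16), so fold changes are on that scale and understate changes of dim genes. Probe sets in the lowest 40 percent by mean, a limit that lay at a signal of 13.3, were left out, and each gene was represented by its probe set of highest mean, leaving 12760 genes. Of these, 6047 genes had more than 1 probe set past the filter, and for named genes the text gives other probe sets where they differ in sign from a printed change. A linear model with 1 mean per group was fitted to all 33 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend and robust). The contrasts were vehicle Tg2576 minus wild type, treated minus vehicle Tg2576, and treated Tg2576 minus wild type. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a limit of 0.05.

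Before the data were examined, 32 gene lists of pathways and cell types were fixed, with 535 distinct genes, of which 501 were named on the array and 448 tested. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, which asks whether the members move one way on balance. The blood cell list had 1 tested member and no test. Per-animal list scores are the mean over members of each animal's deviation from the gene's average, compared by permutation tests with 100000 resamples. Genes named in the text follow a rule fixed at the same time: per comparison the 10 largest rises and 10 largest falls that passed, up to 4 passing members of each list (those of smallest p) or, where none passed, its member of smallest p as a value, and always App, Prnp, Abca1, Apoe, Srebf1 and Gfap.

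The procedure was tested on simulated data with the real genes' means and spreads, for the drug comparison with 12760 genes and 200 of them changed, over 10 draws. It recovered 38.4% of genes changed by 0.25 on the log2 scale, 89.3% of those changed by 0.5 and 99.4% of those changed by 1, and 5.2% of its calls were false. A list shifted by 0.15, cholesterol synthesis and uptake, was called in 10 of 10 draws at the preset correlation. The simulated genes were independent of each other, whereas that list had an estimated correlation of 0.274 on the real arrays. These rates therefore need not hold for the real arrays. Alternatives covered the pseudocount, the filter, the normalization, the probe set rule, the arrays and the covariates entering the fit, the variance model, the replicate number, a rank-sum test by normal approximation and in exact form with ties kept, and each array left out in turn.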

Results

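Gene expression was measured in the right hippocampus of 33 male mice, 1 array per animal, on the Affymetrix MOE430 2.0 platform. Tg2576 mice carry a human APP transgene with the Swedish familial Alzheimer's disease mutation, driven by the prion promoter. TO901317 is a synthetic agonist of the liver X receptors (LXR), nuclear receptors that switch on genes of cholesterol efflux and fatty acid synthesis. The animals were 20 weeks old and formed 3 groups of 11: wild-type littermates given vehicle, Tg2576 mice given vehicle, and Tg2576 mice given TO901317 orally at 50 mg per kg per day. The labels give the length of dosing as 7 days in one place and 5 days in another. Treated wild-type animals were not analysed here, so the drug response could not be compared between genotypes. The values were linear array signals with a trimmed mean of 99.97 on every array and medians between 19.4 and 28.9. No test of RNA quality, array median or carry-over markers between the groups passed (14 permutation tests, smallest adjusted p = 0.388), but vehicle Tg2576 replicates 3 and 4 stood apart in 1 ratio. The log2 ratio of the 3' to the 5' Gapdh probe set, a measure of RNA quality, was 0.11 and 0.08 in these replicates, at most -0.077 on the other 31 arrays, and had an SD of 0.14 in that group against 0.05 in each of the others (n = 11 each). The same ratio for beta-actin did not set them apart. It was 1.2 and 1.275 in these replicates, within the wild-type range of 0.901 to 1.477. Poorer RNA in vehicle Tg2576 as a group is therefore not shown. The number of 11 arrays per group limits the precision.

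The transgene left no clear mark on the probe sets that name App or Prnp. The brightest App probe set read 3790 ± 401 in wild type (SD, n = 11) and 3688 ± 279.8 over both Tg2576 groups (SD, n = 22), a log2 difference of -0.04 (permutation p = 0.428, two-sided). A second bright App probe set was 0.10 higher on the log2 scale in Tg2576 (permutation p = 0.0244), but in the limma fit of vehicle Tg2576 against wild type its adjusted p was 0.811. The brighter Prnp probe set read 3852 ± 301 in wild type and 3857 ± 219 in Tg2576 (permutation p = 0.92). Probe sets designed on the mouse sequence need not read the human transcript, so these values check neither the labels nor the transgene. Xist signals were at most 31.0 on any array, and the brightest Eif2s3y probe set, which reads a Y-linked gene, was at least 96.2 on every array.

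The first comparison asked what the APP transgene changed in vehicle-treated animals. Genes of cholesterol synthesis were higher in Tg2576 hippocampus than in wild type. Fdft1, the squalene synthase gene, rose from 456 ± 43.2 to 681 ± 88.9 (SD, n = 11 each), a log2 change of 0.56 (SE 0.07, limma adjusted p = 8.02e-06). Sqle, which encodes squalene epoxidase, rose by 0.49 on the log2 scale (SE 0.07, adjusted p = 0.000124), and Fdps, the farnesyl diphosphate synthase gene, rose by 0.48 (SE 0.07, adjusted p = 8.89e-05). Of the 20 measured members of the cholesterol synthesis and uptake list, 7 rose, none fell and 13 did not pass, and 15 rose when adjusted over the list alone. The other members that rose were Nsdhl (0.41), Insig1 (0.31), Hsd17b7 (0.29) and Hmgcs1 (0.28), of which Insig1 is named after its values were seen. All 20 members had a log2 change above 0, under each scaling tried as well, and their mean was 0.28. The list passed camera with an adjusted p of 7.08e-25, and with an adjusted p of 0.00186 with an estimated correlation. Averaged per animal, the list score was 0.17 ± 0.09 in vehicle Tg2576 and -0.12 ± 0.08 in wild type (SD, n = 11 each, permutation p = 2e-05, two-sided), and 10 of 11 vehicle Tg2576 animals lay above the highest wild-type animal.

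Across the 12760 genes tested, 30 differed between vehicle Tg2576 and wild type at an adjusted p under 0.05, 16 higher and 14 lower, and none by as much as 2-fold. The largest of these changes was 1.71-fold, for Tdo2, on the log2(signal + 16) scale, which understates changes of dim genes. The mean signal of Tdo2 was 73.2 in wild type and 37.3 in vehicle Tg2576, and that of Met was 15.75 and 30. Higher in Tg2576 beyond the cholesterol genes were Lyz2, a macrophage and microglial lysozyme (log2 change 0.62, adjusted p = 0.0211), Igfbp6, which binds insulin-like growth factors (0.60), Met, the hepatocyte growth factor receptor (0.53), S100a10 (0.47), the neuropeptide gene Nts (0.45) and Cbln2 (0.39). Lower in Tg2576 were Tdo2, which encodes tryptophan dioxygenase (-0.77, adjusted p = 0.00128), Dio2, the deiodinase that activates thyroid hormone (-0.62), Ppp1r3g, a glycogen-targeting phosphatase subunit (-0.55), Mtcp1 (-0.51), 2900052N01Rik (-0.43), Nrarp (-0.39), Timp4 (-0.36), Pbxip1 (-0.36), Ppp1r16b (-0.36) and Hsd11b1, which regenerates active glucocorticoid (-0.35). The second expressed probe set of Tdo2 differed by -0.04 and that of Mtcp1 by 0.02, so these falls rest on 1 probe set each. With the mean of probe sets the value for Mtcp1 was -0.24 and it lost the call. With tissue marker scores as covariates only 2 of the 30 genes kept the call, Fdft1 and S100a10. The other cholesterol genes lost it at values of 0.29 to 0.46. Among the rest that lost it, the values were -0.035 for Timp4, -0.18 for Hsd11b1 and 0.34 for Lyz2. Tdo2 and Slc4a4 lost it too, but they are themselves members of the dentate gyrus and astrocyte scores, so their losses are partly by construction. In 6 genes no Tg2576 vehicle animal overlapped any wild-type animal, namely Fdft1, Fdps, Hmgcs1, Hsd17b7, Sqle and Mtcp1, where chance gives 0.000284% of genes. Gfap, the intermediate filament gene of astrocytes, read 240 ± 49.1 in wild type and 310 ± 88.4 in Tg2576 and did not pass (log2 change 0.33, adjusted p = 0.258).

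**Figure D1:**
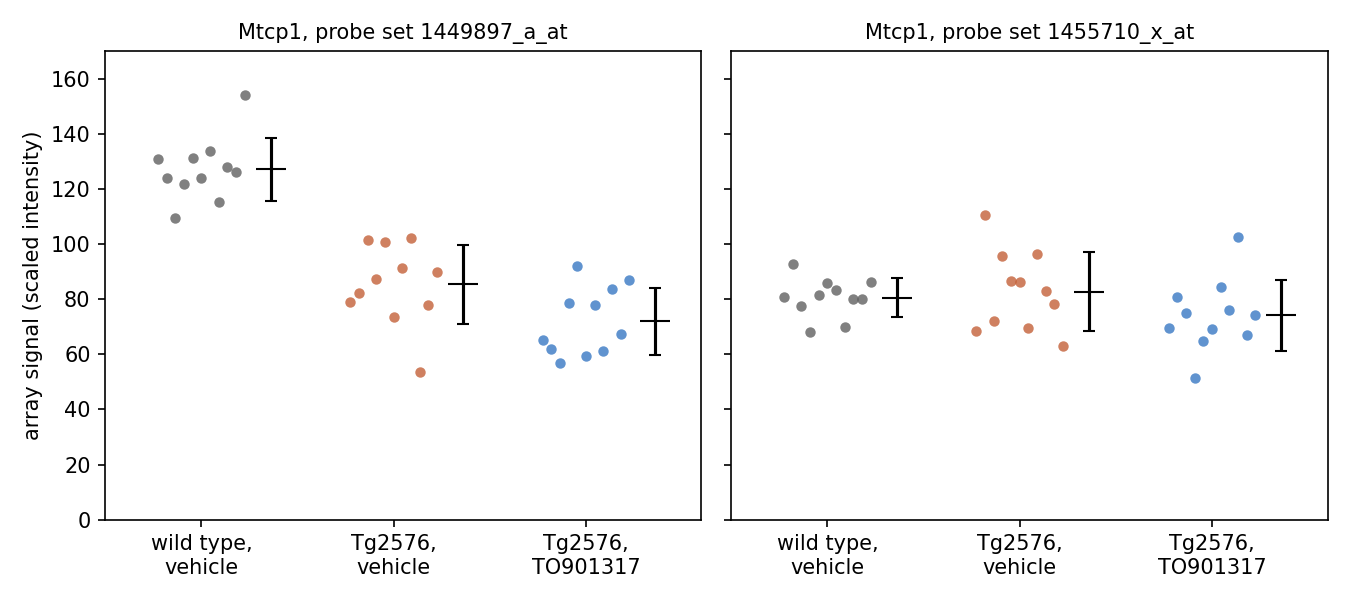
Array signal (scaled intensity, linear axis from 0) of the 2 expressed probe sets that name Mtcp1, with 1 point per animal and the mean with SD bars beside each group of 11. On the left, wild-type animals lie between 109 and 154 and vehicle Tg2576 animals between 53.6 and 102, and on the right the same groups overlap, with means of 80.6 and 82.7.

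Markers of several cell types moved with the genotype, beside the cholesterol genes. Of 16 astrocyte markers, Slc4a4, a bicarbonate transporter, fell by 0.27 on the log2 scale (adjusted p = 0.00177) and 15 did not pass, with 7 falls adjusted over the list alone. The mean over the list was -0.17 (camera adjusted p = 1.32e-09, and adjusted p = 0.0145 with an estimated correlation). Of 12 dentate gyrus markers, Tdo2 fell and 11 did not pass, with 3 falls adjusted over the list alone and a mean of -0.22 (adjusted p = 2.65e-05, and 0.0333 as an adjusted p with an estimated correlation). Of 12 meningeal and fibroblast markers none passed and 1 rose adjusted over the list alone, with a mean of 0.35 (adjusted p = 2.57e-05), and this call was lost with an estimated correlation (adjusted p = 0.24). Slc22a6 had the smallest p of that list, with a log2 change of 0.48 (adjusted p = 0.176). Calls were lost in the same way for reactive astrocyte genes, where S100a10 rose among 9 members and 3 rose adjusted over the list alone (mean 0.21, adjusted p = 0.24 with an estimated correlation), for oligodendrocyte and myelin genes, where none of 17 passed and 3 fell adjusted over the list alone (mean -0.17, adjusted p = 0.249 with an estimated correlation), and for oligodendrocyte precursor genes, where none of 9 passed and 1 fell adjusted over the list alone (mean -0.14, adjusted p = 0.052 with an estimated correlation). Endothelial markers (mean -0.10, 1 fall adjusted over the list alone, Slco1c1 at -0.44) and thalamus and striatum markers (mean 0.14, 2 rises adjusted over the list alone, Slc17a6 at 0.47) were called at the preset correlation only, with an adjusted p of 0.348 and 0.307 with an estimated correlation. LXR target and fatty acid synthesis genes did not pass as lists between the genotypes, with an adjusted p of 0.3 and 0.523, and no member passed over all genes. Adjusted over the list alone, 2 LXR targets fell, and 1 fatty acid synthesis gene rose and 2 fell. Lists of microglia markers, plaque-associated microglia, inflammatory mediators, interferon response and APP processing did not pass, and Lyz2 was the only member of these lists that rose or fell. Of the 31 lists tested, 13 were called at the preset correlation and 3 with an estimated one.

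The limma fit used 1 spread per gene over all 33 arrays, and 1520 genes had an unadjusted p under 0.05 where 638 are expected by chance. The count of 30 became 51 without wild-type replicate 5 and 57 without vehicle Tg2576 replicate 1, 59 with a Gapdh 3' to 5' covariate, 14 without the 3 arrays of lowest correlation, 2 with the tissue marker scores as covariates and 14 in an exact rank-sum test, 12 of them among the 30, while 20 of the 30 calls held with each array left out in turn. Insig1, Lyz2, Met, Nts, Pbxip1, S100a10 and Timp4 were among those that lost the call in at least 1 such fit. Without vehicle Tg2576 replicates 3 and 4, chosen after their Gapdh ratios were seen, 26 genes passed, 18 of them among the 30, the calls of Lyz2, Met, Nrarp, Nts, Pbxip1, S100a10 and Insig1 ended, and the cholesterol score differed by 0.28 (permutation p = 2e-05).

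The next comparison asked what TO901317 changed in Tg2576 hippocampus. Established LXR targets were higher in treated animals. Abca1, the cholesterol efflux transporter, rose from 311 ± 24.0 to 488 ± 89.2 (SD, n = 11 each), a log2 change of 0.61 (SE 0.08, limma adjusted p = 5.83e-05). Srebf1, the master regulator of fatty acid synthesis, rose by 0.63 (SE 0.09, adjusted p = 5.83e-05) with no overlap between the groups, as in 1 other gene, Cyp2d22, where chance gives 0.000284% of genes. Scd1, the stearoyl-CoA desaturase gene, rose by 0.66 (adjusted p = 0.00104), and Abcg1, a second sterol transporter, by 0.42 (adjusted p = 0.000358). Of the 20 measured LXR targets 4 rose, none fell and 16 did not pass, with 8 rises adjusted over the list alone. Their mean was 0.20, and the list passed camera with an adjusted p of 1.55e-11, and of 0.00168 with an estimated correlation. Apoe read 4095 ± 445 in vehicle and 4908 ± 722 in treated animals (log2 change 0.26, adjusted p = 0.134) and did not pass over all genes.

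Averaged over the 20 LXR targets, each of the 11 treated animals lay above the median of the vehicle Tg2576 animals. The mean difference was 0.20 on the log2 scale (permutation p = 4e-05, two-sided, adjusted p = 0.00012 over 6 tests), and it was 0.24 among replicates 1 to 5 and 0.16 among replicates 6 to 11. The same score differed by -0.01 between vehicle Tg2576 and wild type (permutation p = 0.754). Fatty acid synthesis genes gave 3 rises among 20 members, Srebf1, Scd1 and the desaturase gene Fads2 (0.35, adjusted p = 0.0433), and 17 did not pass. Adjusted over the list alone, 6 members rose and 2 fell. That list passed camera (mean 0.13, adjusted p = 1.14e-05), with an adjusted p of 0.0574 with an estimated correlation. It shares members with the LXR target list, Srebf1 and Scd1 among them, and was not tested without these. Its result is therefore not separate from that of the LXR targets.

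**Figure D2:**
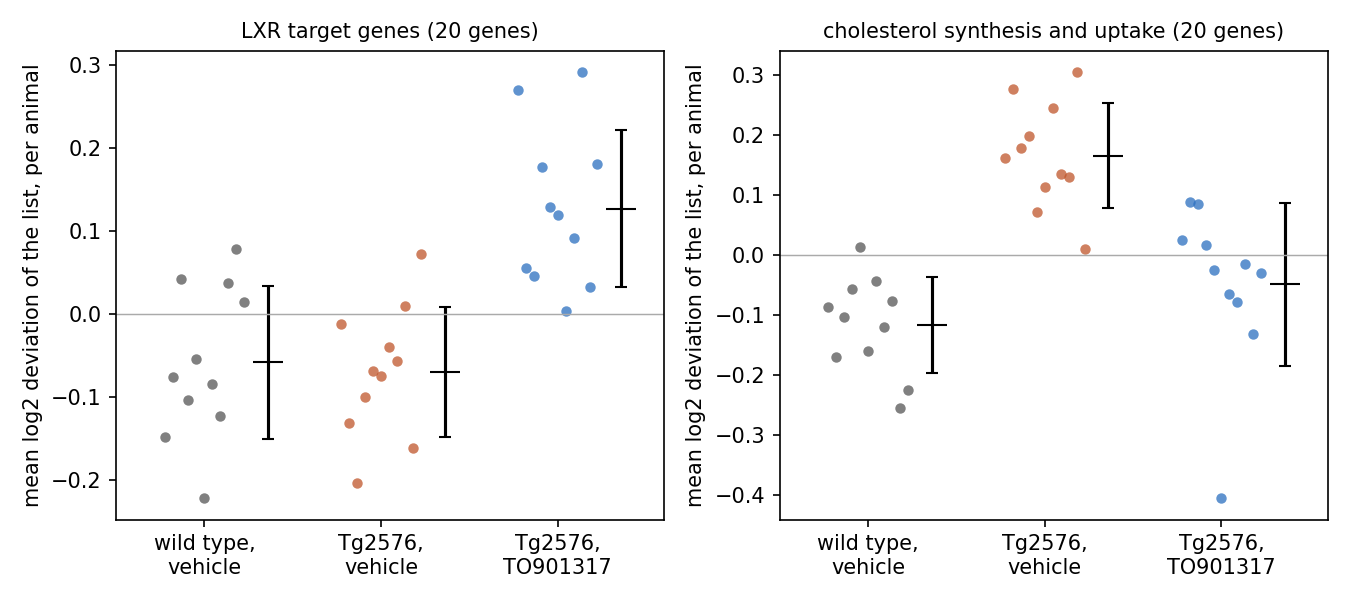
Mean log2 deviation from the all-array average over the 20 measured LXR target genes (left) and the 20 measured cholesterol synthesis and uptake genes (right), with 1 point per animal and the mean with SD bars beside each group of 11. LXR scores average 0.13 in treated animals and -0.07 in vehicle Tg2576 animals, and cholesterol scores average -0.12, 0.17 and -0.05 in wild type, vehicle Tg2576 and treated Tg2576.

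Cholesterol synthesis genes were lower in treated than in vehicle Tg2576 animals. Idi1, the isopentenyl diphosphate isomerase gene, fell by 0.37 on the log2 scale (SE 0.07, adjusted p = 0.0048), Sqle by 0.36 (SE 0.07, adjusted p = 0.0105) and Hmgcs1, the cytosolic HMG-CoA synthase gene, by 0.25 (SE 0.05, adjusted p = 0.00964). Hsd17b7 (-0.22) and Cyp51 (-0.26), the latter named after its values were seen, also fell, so that 5 of 20 members fell, none rose and 15 did not pass, with 13 falls adjusted over the list alone. All 20 members had a log2 change below 0, except that 1 was above 0 when the probe sets of each gene were averaged. The list passed camera with an adjusted p of 7e-16, and of 0.0127 with an estimated correlation. Per animal, the list score differed by -0.21 between treated and vehicle Tg2576 animals (permutation p = 6e-05, two-sided), and the difference was -0.14 among replicates 1 to 5 and -0.28 among replicates 6 to 11. Treated replicate 6 had the lowest score of all animals (-0.41), and without it the difference was -0.18.

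In all, 36 genes passed between treated and vehicle Tg2576, 15 higher and 21 lower. Other rises were Apod, a lipocalin that carries lipids (0.78, adjusted p = 0.0048), the lysophospholipid transporter gene Mfsd2a (0.51), the cytochrome P450 gene Cyp2d22 (0.49), Slco1a4, an organic anion transporter of brain endothelium (0.42), and Hspa2 (0.41). The largest falls were in AI506816 (-1.29, adjusted p = 0.033), from 60.1 ± 25.6 to 15.3 ± 14.9, and in Ly6g6e (-0.70, adjusted p = 0.0101). Further falls were in Rpe (-0.37), Ttc9c (-0.30), Ednrb, the endothelin B receptor (-0.29), Lonp2 (-0.29), Mrpl36 (-0.28) and Pnoc, the prepronociceptin gene (-0.28). The other expressed probe sets of Ednrb ranged from -0.03 to 0.06 and those of Lonp2 from -0.14 to 0.24. Apod was the only member of 18 genes of cholesterol turnover and lipoprotein receptors that rose, and that list did not pass (adjusted p = 0.0505). Endothelial markers passed at the preset correlation (mean 0.16, adjusted p = 3.26e-05), with 1 rise among 13 members, Slco1a4, 4 rises adjusted over the list alone and an adjusted p of 0.132 with an estimated correlation. The xenobiotic response list gave 1 rise among 7 members, again Slco1a4, and 2 adjusted over the list alone (adjusted p = 0.321 with an estimated correlation). Astrocyte markers (mean 0.06), pericyte and smooth muscle markers (mean 0.15) and synaptic genes (mean 0.09) were called at the preset correlation with no member past the threshold over all genes. Adjusted over the list alone, 4 astrocyte markers rose and 1 fell, and 2 synaptic genes rose. These lists had an adjusted p of 0.397, 0.441 and 0.321 with an estimated correlation. Microglial, inflammatory, interferon and APP processing lists did not pass, Gfap had a log2 difference of -0.02 (adjusted p = 0.979), and App of 0.12 (adjusted p = 0.306). Of 31 lists, 10 were called at the preset correlation and 2 with an estimated one.

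At an unadjusted p under 0.05 there were 1497 genes, where 638 are expected. The count of 36 became 22 without treated replicate 1 and 20 without treated replicate 6, 22 with no filter on low signals, 65 with a Gapdh 3' to 5' covariate, 62 with tissue marker scores as covariates and 24 in an exact rank-sum test, 20 of them among the 36, while 18 of the 36 calls, Abca1, Abcg1, Scd1, Srebf1, Hmgcs1, Idi1 and Sqle among them, held with each array left out in turn. Hsd17b7, Fads2, Hspa2 and Rpe lost the call under 9, 9, 10 and 11 of 17 alternatives. Mfsd2a, AI506816 and Pnoc lost it in 14, 14 and 16 of the 22 fits that left out 1 array. Without vehicle Tg2576 replicates 3 and 4, 25 genes passed, 20 of them among the 36, the calls of AI506816, Cyp51, Fads2, Hsd17b7, Hspa2, Lonp2, Mrpl36, Pnoc, Rpe and Slco1a4 ended, and the scores differed by 0.18 for LXR targets (permutation p = 0.00023) and -0.21 for cholesterol genes (permutation p = 0.00027).

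Treated Tg2576 animals were also set against wild type, where genotype and drug differ together. The treated arrays are those of the drug comparison, so the rises of LXR targets here are not an independent result. Srebf1 was higher by 0.69, Scd1 by 0.64 and Abca1 by 0.55 on the log2 scale, and Apoc1, an apolipoprotein gene, by 0.71 (adjusted p = 0.0322). Of 20 LXR targets 4 rose and none fell, with 6 rises adjusted over the list alone, and this was the 1 list of 31 called with an estimated correlation (adjusted p = 0.00919), against 14 at the preset correlation. Cholesterol synthesis genes gave 1 rise among 20, Fdft1 (0.30, adjusted p = 0.0398), and 3 adjusted over the list alone. The list mean was 0.07, with a camera adjusted p of 0.00856 and an adjusted p of 0.453 with an estimated correlation. The per-animal score of that list differed by 0.07 (permutation p = 0.171), and this depended on treated replicate 6, the animal of lowest score: without it, a choice made after its score was seen, the difference was 0.10 (permutation p = 0.00537). The other calls at the preset correlation were lost too, although fry kept the fatty acid synthesis, astrocyte, dentate gyrus and unfolded protein lists. With an estimated correlation the adjusted p was 0.17 for fatty acid synthesis, 0.336 for xenobiotic response, 0.272 for interferon response, 0.18 for astrocyte markers and 0.612 for oligodendrocyte and myelin genes. It was 0.472 for endothelial markers, 0.453 for pericytes, 0.612 for meningeal markers, 0.336 for interneuron markers, 0.17 for dentate gyrus markers, 0.227 for immediate early genes and 0.17 for the unfolded protein list. Adjusted over the list alone, 8 unfolded protein genes, 5 astrocyte markers, 4 immediate early genes and 3 dentate gyrus markers fell. Of interneuron markers 5 fell and 1 rose, of fatty acid synthesis genes 4 rose and 1 fell, and 3 pericyte markers rose. Apod (0.96), Vwf, the von Willebrand factor gene (0.66), Spaca6 (0.59), Sbsn (0.54), Tfrc, the transferrin receptor (0.39), and Tti2 (0.39) rose as well. Among falls were Fabp7, a fatty acid binding protein of astrocytes and radial glia (-0.93, adjusted p = 0.00377), Mtcp1 (-0.71), Dio2 (-0.56), the neuropeptide genes Npy (-0.55) and Vgf (-0.35), Nrarp (-0.46), Gpr17 (-0.40), Lcat (-0.37), Slc6a7 (-0.36), Lrrtm4 (-0.35) and Slc4a4 (-0.29). The other expressed probe set of Mtcp1 was at -0.11. For Tti2 the other 4 expressed probe sets ranged from -0.32 to 0.01, and its change reversed to -0.04 with the mean of probe sets. Gpr17 and Lrrtm4 lost the call under 11 and 7 of 17 alternatives and in 18 and 17 of the 22 fits that left out 1 array. With tissue marker scores as covariates 14 of the 46 genes that passed in this comparison kept the call. Fdft1, Apoc1, Spaca6, Sbsn, Tti2, Fabp7, Npy, Vgf, Gpr17, Lcat and Lrrtm4 lost it. The values were -0.21 for Gpr17, -0.23 for Lrrtm4, -0.13 for Lcat, 0.24 for Sbsn, 0.51 for Apoc1, -0.81 for Fabp7 and -0.42 for Npy.

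In total 46 genes passed in this comparison, 18 higher and 28 lower. Of these, 7 were among the 30 genes of the genotype comparison and 9 among the 36 of the drug comparison, each in the same direction, and 30 were in neither. The wild-type arrays are shared with the genotype comparison and the treated arrays with the drug comparison, each with the same sign. This alone favours the same direction, so the overlap is not independent support. The count fell to 24, 28, 28, 22, 27 and 30 without wild-type replicates 1, 3, 6, 9, 10 and 11, to 25, 28, 24, 23, 28 and 27 without treated replicates 2, 4, 5, 6, 8 and 9, with 19 of the 46 calls held with each array left out in turn, and to 26 in an exact rank-sum test, 21 of them among the 46. It was 82 with array weights and 27 with the tissue marker scores as covariates, 14 of these 27 among the 46.

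The drug and genotype changes were then compared gene by gene. Hmgcs1, Hsd17b7 and Sqle were higher in vehicle Tg2576 than in wild type and lower in treated than in vehicle Tg2576. Both comparisons use the same vehicle Tg2576 arrays with opposite sign, which alone makes their changes oppose. Across all 12760 genes the correlation of the log2 changes was -0.577, and simulated unchanged groups with the same shared arrays gave -0.497 ± 0.011 (SD, 100 draws). Whole arrays shuffled over the groups gave -0.514 ± 0.095. The covariance was -0.00816, against -0.00452 ± 0.000158 in the simulation and -0.00452 ± 0.00129 with shuffled whole arrays (SD). With the vehicle arrays split it was -0.00403 and -0.00336, against 0.00023 ± 0.00167 for shuffled arrays. With the vehicle arrays split so that no array served both comparisons, the correlation was -0.218 and -0.176 for the 2 ways of splitting, and shuffled arrays with the same split gave 0.017 ± 0.124 with a lowest value of -0.271, so both values lay within the range of shuffled arrays. These correlations are across genes, which are not independent replicates. With genes called on the 6 odd-numbered vehicle animals alone, 7 of 9 had the opposite sign under the drug in the even-numbered ones. With the sets exchanged 16 of 23 did. Over all genes 57.3% and 54.9% had opposite signs under the same splits, and the counts were not tested against these shares.

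**Figure D3:**
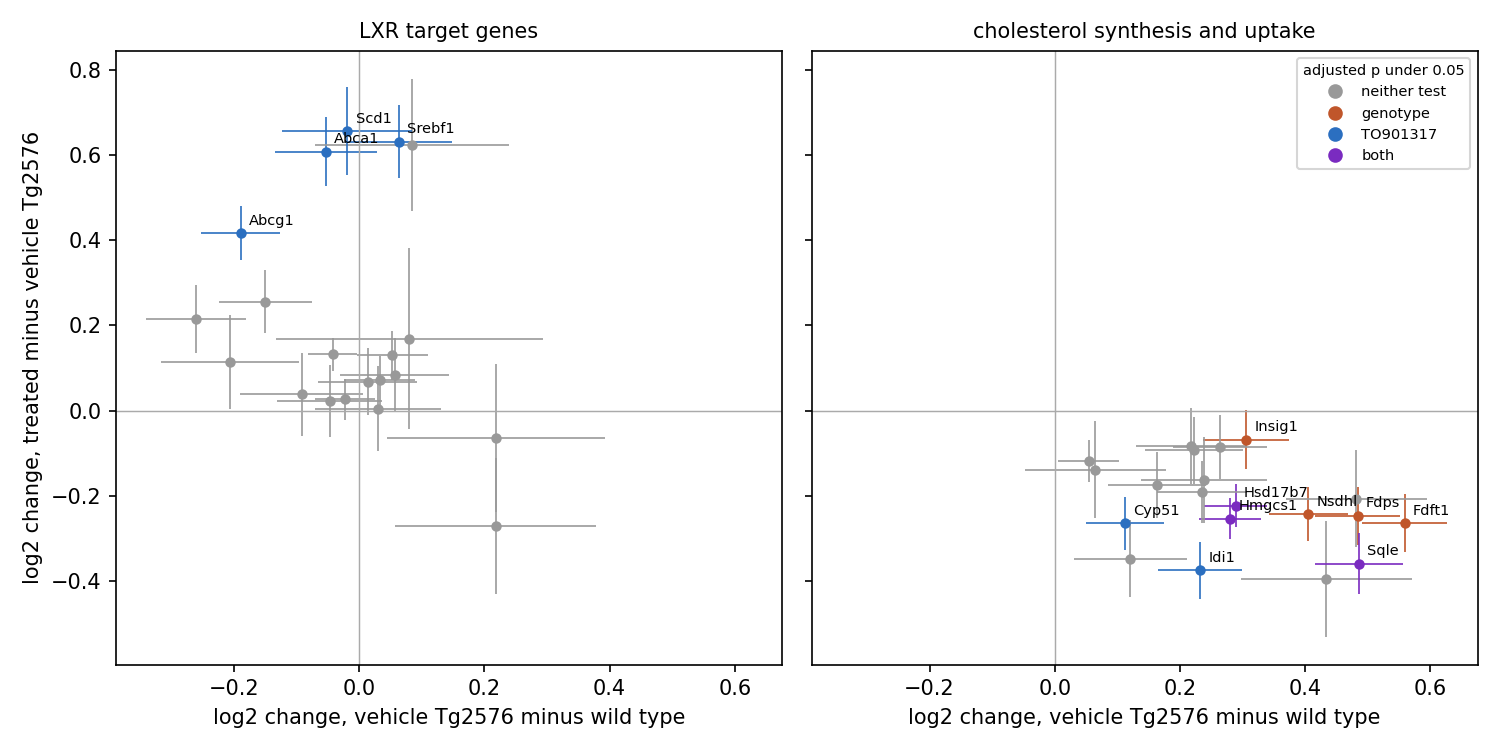
Log2 change of each measured LXR target (left) and cholesterol synthesis and uptake gene (right), with the change from wild type to vehicle Tg2576 on the x axis and from vehicle to treated Tg2576 on the y axis, bars of 1 SE and colours for an adjusted p under 0.05. All 20 cholesterol genes lie to the right of 0 and below 0, and the vehicle Tg2576 arrays enter both axes.

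For the cholesterol list the opposition held with separate vehicle arrays. Using the 6 odd-numbered vehicle animals for the genotype and the 5 even-numbered ones for the drug, 19 of 20 members were higher by genotype (mean 0.25) and 20 of 20 lower with the drug (mean -0.25). With the sets of vehicle animals exchanged, 20 of 20 were higher by genotype (mean 0.32) and 19 of 20 lower with the drug (mean -0.18).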

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

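Of the tests here, those of clock phase, of separate handling and of the second Mtcp1 probe set were chosen after the result was seen, as was the interval used to judge the genes beside Mtcp1. Probe sets that name no single gene here stayed outside the gene-level comparisons. When every probe set was tested, 5 of these 3984 passed between vehicle Tg2576 and wild type, 7 between treated and vehicle Tg2576, and 5 between treated Tg2576 and wild type. They are given as counts with no explanation. The outlier screen was not run, since it covers at most 10 samples per group.

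Cholesterol synthesis genes stood higher in vehicle Tg2576 than in both other groups, by 0.28 (SE 0.04) against wild type, and treated animals differed from vehicle Tg2576 by -0.21 (SE 0.04). A different share of astrocytes, oligodendrocytes, meninges or dentate gyrus in the tissue is argued against as the whole cause, because with these marker scores as covariates the shifts were 0.31 (SE 0.07) and -0.23 (SE 0.05). A different time of killing could not be decided. The clock phase score differed by -0.15 for genotype (permutation p = 0.0796) and 0.21 for the drug (permutation p = 0.00461). Adjusting for it left 0.275 and -0.204, and the slope within groups was -0.05 (SE 0.11) where slopes of -1.91 and -1.04 would be needed. This argues against a linear tie of the 2 scores among animals of a group. A time that differed only between the groups is not tested by a slope within them. Separate handling of the vehicle Tg2576 group cannot be told apart from genotype and drug, because every such animal is in 1 group, and the smaller shift over the 2 sets of odd and even vehicle arrays was 0.249 for genotype and -0.181 for the drug. A response to the transgene that the LXR agonist offsets may be offered as a hypothesis only, and treated wild-type animals or randomised handling, neither of them analysed here, would be needed to decide it.

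The brighter probe set that names Mtcp1 was lower in every Tg2576 animal than in every wild-type animal. The other expressed probe set differed by 0.022 (SE 0.08), which fits a difference in the sequence or transcript that the first one reads. Probe sequences were not examined, so what the other probe set reads is not known and its value cannot decide this. Of the 20 nearest tested genes 1 had an unadjusted p under 0.05, with an upper 95% limit of 4.97, where 2.38 are expected and 6 would exceed chance. This argues against a block of neighbouring genes whose expression changed together. A carried block that leaves the expression of the neighbours unchanged would not show in this count and stays open. A variant at the gene itself, or regulation by the transgene, stays open and was not tested.

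Arrays of different groups with neighbouring replicate numbers deviated together: the correlation of their residual correlation with the distance in number was -0.419 over 363 pairs (p = 1e-04, the smallest that 10000 shuffles can give). With both 3' to 5' ratios as covariates this correlation was -0.255 (p = 2e-04). This argues against RNA degradation, as far as these ratios measure it, as the whole cause, but it may account for part. Choroid plexus carry-over took more of the correlation, leaving -0.159 (p = 0.004), and may also account for part. Array scaling left -0.405 after quantile normalization (p = 1e-04). The labels do not say what the numbers stand for, so an order of dissection or hybridisation stays open, and no biological explanation was tested.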

How the results depend on the processing

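The replicate number as a numeric covariate, the 4 tissue scores, the fits without the 3 arrays of lowest correlation or the 2 of highest Gapdh 3' to 5' ratio, the exact rank-sum test and all alternatives for the cholesterol score were chosen after seeing the data. Between treated and vehicle Tg2576, the LXR score kept its sign and a p under 0.05 under the alternatives for the pseudocount, filter, normalization, probe sets, member median, tissue scores and doubted arrays and without its fatty acid members (0.157 to 0.245), as did the cholesterol score under those run on it (-0.234 to -0.178). Sets of replicate numbers, with fewer animals and no test, gave a wider range for the cholesterol score (-0.277 to -0.139). Of 2635 values of named genes under 17 alternatives, 2446 kept direction and side, 164 lost and 24 gained the call, and Tti2, treated against wild type, reversed to -0.041 with the mean of probe sets. The median gene moved by under 0.1 under every scaling. Counts that moved by over 1.5 times, in the order genotype (30), drug (36) and treated against wild type (46), were as follows. With no filter, 22 and 26 (drug, treated). Without trend and robust, 29 (treated). With array weights, 82 (treated). With the Gapdh covariate, 59 and 65 (genotype, drug). With the numeric covariate, 56 and 70 (genotype, treated). Without those 3 arrays, 14 (genotype). With tissue scores, 2, 62 and 27. The exact rank-sum test called 14, 24 (not over 1.5 times) and 26, with 1237, 1279 and 1282 genes at an unadjusted p under 0.05. Its normal approximation called 0, 0 and 0, which says nothing about stability, because that approximation gives no p below 8.15e-05 with 11 animals per group, where the exact test reaches 2.84e-06. With tissue scores all 30 genotype genes kept their sign, with a median size of 0.41 against 0.39 and a median SE of 0.11 against 0.07, since genotype shares an R2 of 0.441 with the dentate and 0.486 with the astrocyte score. Not every call ended through the SE alone: Timp4 went from -0.36 to -0.035, Hsd11b1 from -0.35 to -0.18, Lyz2 from 0.62 to 0.34 and, named after their values were seen, Adcy1 from -0.26 to -0.11 and Ppp1r3c from -0.26 to -0.11. Leaving out 1 array gave 23 to 57, 20 to 43 and 22 to 50. With the replicate number as a block there were 51 genes for genotype, 31 for the drug and 65 for treated against wild type, and the block ended 11 calls of named genes, for the drug AI506816, Hsd17b7, Mfsd2a, Hspa2, Fads2, Pnoc and Rpe, and for treated against wild type Vgf, Apoc1, Tti2 and Gpr17. The labels give the numbers no meaning, and 1, 3 and 6 of 11 same-numbered pairs had a residual correlation above 0.1. Their means were 0.026, 0.069 and 0.099, against -0.002, -0.007 and -0.01 for other pairs. All 11 pairs of vehicle and treated Tg2576 were above 0 (lowest 0.041). The numbers were not taken as a pairing, so the main fit leaves out any order that the groups share. Not every array correlated best with its own number. Lists called fell from 13, 10 and 14 to 3, 2 and 1 with an estimated correlation and to 5, 3 and 5 with fry. Those that only fry kept were oligodendrocyte precursors (fry adjusted p = 0.0126) and the clock (0.0241) by genotype, and fatty acid synthesis by drug (0.00735). For treated against wild type they were fatty acid synthesis (0.0389) and the astrocyte, dentate gyrus and unfolded protein lists (0.0491 each). The opposition of -0.577 became -0.218 and -0.176 with split vehicle arrays, by construction, and kept its direction with a pseudocount of 64 and after quantile normalization. For the other moved counts the cause was not tested. Dim genes near the filter limit of 13.3 are measured least well.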

Other observations

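The tests of splits and of the relation between the scores were written before their results were seen, but the rule that left the relation undecided was set afterwards. The circadian clock list had a mean of -0.13 by genotype and of 0.08 by drug. Per3 fell by 0.32 on the log2 scale in vehicle Tg2576 against wild type (limma adjusted p = 0.0127), the only member of 14 to pass, with 5 falls and 1 rise adjusted over the list alone. Dbp (-0.26), Per2 (-0.26) and Tef (-0.16) did not pass over all genes, nor did Arntl (0.19), which peaks in the opposite phase, and these 4 genes are named after their values were seen. In treated against vehicle Tg2576, Per3 was at 0.27 (adjusted p = 0.0664) and none of the 14 passed, with 2 rises adjusted over the list alone. The clock list was called at the preset correlation in both comparisons, with an adjusted p of 0.09 and 0.207 with an estimated correlation. Since both comparisons share the vehicle arrays, opposite signs also arise by chance.

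Activity and stress lists were lower in vehicle Tg2576 at the preset correlation only. Adjusted over the lists alone, 3 immediate early genes fell, 1 unfolded protein gene rose and 1 fell, and no glucocorticoid gene did. Immediate early genes had a mean of -0.13 with Dusp6 at -0.35 (adjusted p = 0.068), the unfolded protein list a mean of -0.11 with Sdf2l1 at -0.51 (adjusted p = 0.0696), and the glucocorticoid list a mean of -0.15 with Tsc22d3 at -0.24 (adjusted p = 0.291, with its other expressed probe sets at -0.34 and 0.20), and with an estimated correlation their adjusted p was 0.169, 0.24 and 0.24. The glucocorticoid list had a mean of 0.19 with the drug (adjusted p = 0.207 with an estimated correlation), with Plin4 at 0.73 (adjusted p = 0.223). Camk2a, the gene of a synaptic kinase, read 3219 ± 479, 2393 ± 558 and 3151 ± 278 in wild type, vehicle Tg2576 and treated Tg2576, and just missed the threshold for genotype (adjusted p = 0.0529) and for the drug (adjusted p = 0.0708). Choroid plexus markers varied widely between animals: Ttr read 2402 ± 2380 in vehicle and 3457 ± 2293 in treated Tg2576, and that list did not pass in any comparison. The lists of CA1 to CA3 pyramidal, neurogenesis, heat shock, oxidative phosphorylation and lysosome genes passed in no comparison, and no member of them passed over all genes. Adjusted over the list alone, Tubb3 (0.22), named after its values were seen, rose and Neurod1 (-0.24) fell among neurogenesis genes by genotype. In the same way Hsph1 fell among heat shock genes by drug (-0.21) and in treated Tg2576 against wild type (-0.19), and of the lysosome genes Hexa fell by drug (-0.19) and Neu1 rose in treated Tg2576 against wild type (0.23). Median, mean and test differed in sign for APP processing, xenobiotic, pericyte, oxidative phosphorylation and lysosome genes by genotype, for CA1 to CA3, immediate early and heat shock genes by drug, and for APP processing, microglia and heat shock genes in treated animals against wild type, and none of these was called in the comparison named. The blood cell list had 1 tested gene, Ngp, at 0.19 by genotype (adjusted p = 0.557). Interneuron markers passed at the preset correlation between treated Tg2576 and wild type (mean -0.12, adjusted p = 0.336 with an estimated correlation), where Npy fell.

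Other splits of the 22 arrays compared bear on chance. For genotype, 2 of 100 splits gave at least 30 genes, the real one included, and the highest other gave 54. For the drug, 1 of 100 gave as many as 36, and the highest other gave 1. For treated against wild type, 2 of 100 gave at least 46, and the highest other gave 135. In each, the share of splits with as many genes was under 0.05, so a random grouping rarely gave such a count. The splits with 54 and 135 genes point to a structure among the arrays other than the groups. That this structure adds to the counts for genotype and for treated against wild type cannot be excluded by these splits.

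It was hypothesised that treated animals with a stronger LXR response would have lower cholesterol synthesis expression. Among the 11 treated animals, Pearson's r between the scores was 0.104 (permutation p = 0.773) and Spearman's rho 0.227 (permutation p = 0.503), and r was -0.086 without the 2 animals farthest from the median, so r lay within its spread of 0 and the relation could not be decided. The other groups gave r = -0.653 in vehicle Tg2576 (permutation p = 0.029, adjusted p = 0.087 over 3 tests, rho -0.6 with permutation p = 0.0566, and r = -0.613 without the 2 farthest) and r = -0.273 in wild type (permutation p = 0.415, adjusted p = 0.622, rho -0.209 with permutation p = 0.541, and r = -0.228 without the 2 farthest).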
